A study of Mus musculus with 8 samples.

How the data were processed

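RNA sequencing was run on 8 libraries of mouse cardiac fibroblasts, the matrix-producing cells of the heart, collected at day 7. The labels divide them into 4 groups of 2 libraries. Cells carried a control vector or overexpressed EphrinB2, a membrane-bound ligand of Eph receptors encoded by Efnb2. Each kind of cell was kept in complete medium or in osteogenic differentiation medium. Total RNA was extracted with Trizol, per the labels' protocols. No label gives a culture, animal, batch or replicate number shared between groups, so libraries were numbered 1 and 2 within a group in listed order and nothing was paired. Nothing states that both libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

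The deposited table holds 1 FPKM value (fragments per exon length and counted reads, a unit that corrects for gene length and depth) for each of 54532 Ensembl genes in each of the 8 libraries. Per the submitters' processing notes the authors used CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 with build mm10. The annotation release, strand setting, counting parameters and any filter are not given in the sources used here. No column held values of other samples. Gene symbols, places and merged exon lengths came from GENCODE M21 on GRCm38, the same assembly as mm10. Of the file's identifiers, 54409 matched that annotation and 123 did not.

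FPKM values are not counts, so no count model was used. The depth was estimated from the steps between low values. FPKM multiplied by merged exon length was a whole multiple of 1 step per library for 98.1% to 98.3% of genes under 50 reads, with a tolerance of 0.02 reads. The step gave 18745719 and 18608295 counted reads in the vector libraries in complete medium and 19355870 and 19359384 in osteogenic medium. In EphrinB2 libraries it gave 19310396 and 16493963 in complete and 20550770 and 19282752 in osteogenic medium. Read numbers given for a gene are estimates from this step and carry counting error only. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and near-identical paralogs may share reads.

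Genes with FPKM of at least 1 in at least 2 of the 8 libraries were tested, which left 12994. Values were analysed as log2(FPKM + 1), and every fold change is on that scale, which understates the change of low genes. All 8 libraries entered 1 linear model with a mean for each group in limma 3.58.1 (R 4.3.3), with moderated two-sided tests and a mean-variance trend. The model had 4 residual degrees of freedom and a prior of 2.72. It assumes the same spread in every group. The comparisons were osteogenic against complete medium in vector cells and in EphrinB2 cells, EphrinB2 against vector in each medium, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Genes are called risen or fallen where they passed it.

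The design, the tests, 33 gene lists and the alternatives planned were fixed before the data were examined. The lists cover signalling pathways, bone and cartilage genes, metabolism, stress, and markers of other cell types of the heart. They were tested with camera in limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The second form also takes its degrees of freedom from the model (4), while the first takes them from the number of genes. It can therefore be stricter even where the estimated correlation lies below the preset one. A list that passes only the first form need not hold genes that move together. The list p-values were adjusted over the 32 lists with enough measured members. The lymphocyte list had 1 measured member and no list test. Genes named in the text follow a fixed rule. It takes Efnb2 in every comparison. For each medium or EphrinB2 comparison it takes the 6 largest rises and 6 largest falls past the threshold with groups that do not overlap and a mean FPKM of at least 2, passing over unnamed genes and pseudogenes, and 3 and 3 for the interaction. It also takes up to 4 called members of each list that passed its test or had at least 3 called members. Finally it takes 3 members with the smallest p of the osteoblast, Eph and ephrin, S100 and RAGE, and myofibroblast lists. Genes outside the rule are marked where they appear, and 1 gene that the rule takes is not reported here.

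The steps were tested on simulated data with the real genes' means and each group's own spread, which depended on the mean alone. Real genes of like mean differ in spread, so their recovery can differ. In each simulated comparison 200 of 12994 genes were changed, all with a mean FPKM of at least 5. The noise was independent and held no trend on gene length. In the simulated comparison of media in vector cells, 0 of 100 genes changed 2-fold and 86 of 100 changed 4-fold were recovered, with 0 unchanged genes called. For EphrinB2 against vector in complete medium 12 of 100 and 79 of 100 were recovered, with 0 false calls. In osteogenic medium 16 and 87 of 100 were recovered, with 3 false calls. For the media in EphrinB2 cells 13 and 83 of 100 were recovered, with 38 false calls among 12994 genes, since the shared spread is too small for the noisier group. The simulated interaction recovered 0 of 100 at 2-fold and 0 of 100 at 4-fold. The cholesterol synthesis list with all members lowered 2-fold was recovered in each of the 5 simulated comparisons, with no other list called.

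Alternatives changed 1 choice at a time. Those planned were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, rescaling to a common total per library, centring on the median, quantile normalization, no mean-variance trend, a robust prior, a model of the 2 compared groups alone, a fold threshold of 2, and leaving out each library in turn. Those chosen after seeing the data were a correction of each library for a trend on gene length (loess, span 0.3), the same with GC content, leaving out 2 EphrinB2 libraries that stood apart from their partners, a variance weight per library, and protein-coding genes only. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.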

Results

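Gene expression was measured by RNA sequencing in mouse cardiac fibroblasts that carried a control vector or overexpressed EphrinB2, each kept in complete or osteogenic differentiation medium and collected at day 7. Each of the 4 groups had 2 libraries, with 16493963 to 20550770 counted reads per library as estimated from the deposited FPKM values. Between 11717 and 12125 genes reached 1 FPKM in a library. The vector libraries lay close to their partners. The SD of the log2 difference between both libraries of a group, over the 12994 tested genes, was 0.26 in complete and 0.23 in osteogenic medium. In EphrinB2 cells it was 0.52 in complete and 0.66 in osteogenic medium. There, the difference between partners rose with gene length (Spearman's rho across genes, which are not independent replicates, 0.44 and 0.51). EphrinB2 complete replicate 2 and EphrinB2 osteogenic replicate 1 are called the libraries that stood apart. Each lay farther than its partner from the vector libraries of its medium. On the first principal component, the axis of largest variation, they stood at -50.51 and 63.33 and their partners at -22.9 and 24.5. Vector libraries stood at -29.55 and -29.59 in complete and at 21.68 and 23.05 in osteogenic medium. Leaving out those that stood apart keeps the EphrinB2 libraries nearer to vector, which by itself can shrink the EphrinB2 effects.

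**Figure D1:**
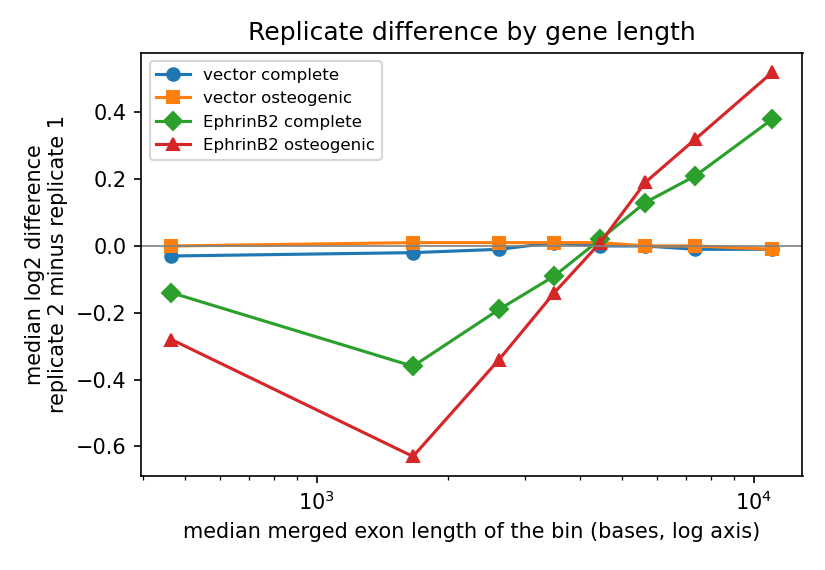
Median log2 difference between replicate 2 and replicate 1 of each group (y axis) in 8 bins of genes ordered by merged exon length (x axis, bases, log scale). Both vector groups stay within 0.03 of 0 in every bin, while the EphrinB2 groups run from -0.36 and -0.63 in the second bin to 0.38 and 0.52 in the longest.

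Efnb2, the overexpressed gene (ENSMUSG00000001300, GRCm38 chromosome 8, 8617434 to 8661242, minus strand), was measured first as a check of the labels. It stood at 5.93 ± 0.521 FPKM (SD, n = 2) in vector cells and 32.1 ± 1.12 in EphrinB2 cells in complete medium. In osteogenic medium it stood at 1.33 ± 0.0908 in vector cells. The EphrinB2 libraries in osteogenic medium differed from each other, with 5.02 FPKM in replicate 1 and 18.3 in replicate 2. Every EphrinB2 library lay above both vector libraries of the same medium, and replicate 1 in osteogenic medium lay below both vector libraries kept in complete medium. The log2 difference between EphrinB2 and vector cells was 2.26 (SE 0.48) in complete and 2.21 (SE 0.48) in osteogenic medium, and neither passed the threshold over all genes (limma, adjusted p = 1.0 and 0.567). Without the libraries that stood apart both passed, at 2.22 (adjusted p = 0.0288) and 3.05 (adjusted p = 0.0118). That leaves 1 library in each EphrinB2 group, which is assumed to vary as little as the vector libraries that alone give the spread, although EphrinB2 partners differed more. Osteogenic medium went with less Efnb2, by -1.57 in vector cells (adjusted p = 0.116) and -1.62 in EphrinB2 cells (adjusted p = 0.0764). In a model of the vector libraries alone the first of these fell past the threshold (adjusted p = 0.000596), and without the libraries that stood apart, with 1 EphrinB2 library against 1, the second was -0.74 (adjusted p = 0.0095, with the spread of the vector libraries alone). Leaving out EphrinB2 osteogenic replicate 1 alone gave 3.05 for EphrinB2 against vector in osteogenic medium and -0.78 for the medium in EphrinB2 cells, and leaving out replicate 2 gave 1.37 and -2.46. Over its span 3 other annotated genes lie on the same strand, and the strand setting is not given in the sources used here.

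**Figure D2:**
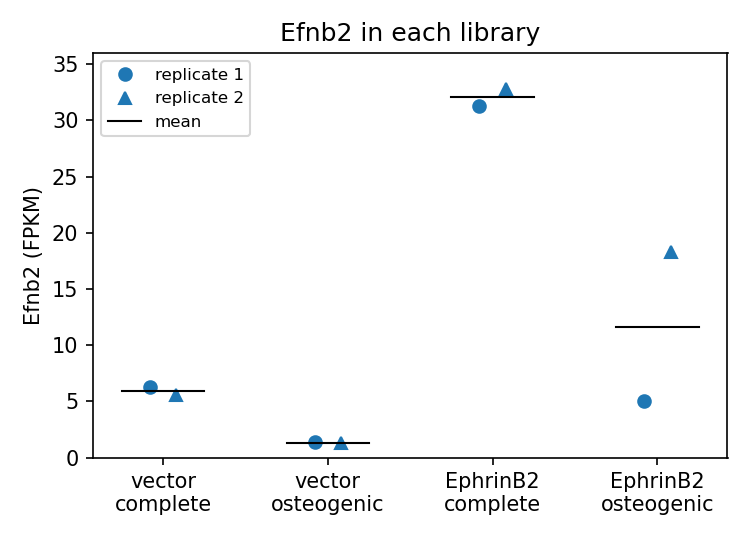
Efnb2 in FPKM (y axis) in each of the 8 libraries by group, with circles for replicate 1, triangles for replicate 2 and a line for the mean of 2. EphrinB2 complete libraries sit at 31.3 and 32.8, EphrinB2 osteogenic libraries at 5.02 and 18.3, and all 4 vector libraries at or below 6.3.

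Osteogenic against complete medium in vector cells asks how cultures of control cells differed between the media. The RNA is that of the whole culture, in which macrophage markers were present already in complete medium. These values therefore do not tell which cells changed. Most glucocorticoid-response genes rose and most cholesterol synthesis genes fell, 19 of 41 collagen and matrix genes fell and 9 of 21 macrophage markers rose, while 5 of 13 osteoblast genes passed the threshold, of which 4 fell. With an estimated correlation the matrix, macrophage and osteoblast lists had adjusted p = 0.157, 0.137 and 0.174. In all, 573 genes rose and 404 fell (limma, 977 of 12994), of which 405 and 275 by at least 2-fold. Among the rises with the largest log2 fold change were the clotting factor subunit F13a1 (6.27, SE 0.18), Ms4a4a (5.83, SE 0.35), the hyaluronan receptor Lyve1 (5.43, SE 0.19), the carbonyl reductase Cbr2 (5.23, SE 0.31) and Fmo2 (5.15, SE 0.27). Lyve1 went from 0.147 ± 0.0267 to 48.5 ± 2.66 FPKM (SD, n = 2). The deepest falls were those of the basement membrane collagen Col15a1 (-4.18, SE 0.21), the granin Scg2 (-3.74, SE 0.32), Cthrc1 (-3.62, SE 0.28), the matricellular protein Ccn4 (-3.60, SE 0.17), the thyroid hormone deiodinase Dio3 (-3.57, SE 0.19) and elastin, Eln (-3.33, SE 0.19). Adjusted p-values of these 11 genes ran from 5.29e-05 to 0.00139.

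Of 20 measured genes of the glucocorticoid-response list, 17 rose and 0 fell (19 rose adjusted over the list alone). The median log2 fold change was 2.72. Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose from 1.55 ± 0.22 to 35.8 ± 0.794 FPKM (SD, n = 2), a log2 fold change of 3.85 (SE 0.14). The kinase Sgk1 rose by 3.03, the cell cycle inhibitor Cdkn1c by 4.62 and the transcription factor Klf15 by 2.83. The list stood above other genes by camera (adjusted p = 2.04e-24), also with an estimated correlation (adjusted p = 0.00876). In the cholesterol synthesis list 18 of 23 measured genes fell and 0 rose (21 fell adjusted over the list alone), with a median of -1.22. Hmgcs1, which makes HMG-CoA, fell from 40.4 ± 0.853 to 9.86 ± 1.05 FPKM (SD, n = 2; log2 -1.93). Insig1, a sterol sensor protein (-1.57), Sqle, the squalene epoxidase (-1.52), and Cyp51, a lanosterol demethylase (-1.80), also fell. This list also held with an estimated correlation (adjusted p = 0.00876; 6.08e-20 with the preset one). These were the 2 lists that did so, out of 16 past the threshold with the preset correlation. The form with an estimated correlation also has fewer degrees of freedom, so the other lists need not owe their loss to correlated genes. The osteoblast and adipocyte lists, for example, had estimated correlations of -0.056 and -0.128, below the preset 0.01.

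Among 41 measured collagen and matrix genes 19 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -1.02. Eln fell from 121 ± 8.3 to 11.1 ± 0.229 FPKM (SD, n = 2), and the collagen Col8a2 (-2.51), the matricellular protein Postn (-2.20) and the prolyl hydroxylase P4ha3 (-1.83) fell too. The list was lower by camera (adjusted p = 6.08e-20), with an adjusted p of 0.157 with an estimated correlation. In the myofibroblast and contractile list 4 of 23 fell, Cthrc1, the collagen receptor subunit Itga11 (-2.38), Tagln2 (-1.29) and Cald1 (-1.18), and 0 rose (10 fell and 2 rose adjusted over the list alone; list adjusted p = 4.47e-05, and adjusted p = 0.136 with an estimated correlation). Of 22 TGF-beta target genes 7 fell and 1 rose, with falls of Bhlhe40 (-2.46), Ccn4 and Pmepa1 (-1.51) and a rise of Tgfbi (1.34). Of 11 Wnt target genes 5 fell and 0 rose, among them the Wnt inhibitors Nkd2 (-1.84), Apcdd1 (-1.86) and Sfrp1 (-1.47). Adjusted over the list alone 9 TGF-beta targets fell and 2 rose, and 8 Wnt targets fell. These lists had adjusted p-values of 0.000203 and 3.59e-06, and each an adjusted p of 0.157 with an estimated correlation. Cell cycle genes fell in 9 of 35 cases and rose in 0, with falls of Prc1 (-1.02), Kif20a (-1.03), Tpx2 (-1.05) and Ccna2 (-1.02), all below 6 FPKM in complete medium (17 fell adjusted over the list alone; list adjusted p = 5.64e-12, and adjusted p = 0.157 with an estimated correlation).

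The osteoblast list had 13 measured members of 30. The small leucine-rich proteoglycan Omd rose, from 1.96 ± 0.074 to 8.72 ± 0.372 FPKM (SD, n = 2; log2 1.71). The cadherin Cdh11 fell from 21.4 ± 0.233 to 3.11 ± 0.369 FPKM (log2 -2.45), and Col1a1 (-1.74), the collagenase Mmp13 (-0.99) and Sparc (-1.73), the last named after its values were seen, also fell. Adjusted over the list alone, likewise 1 rose and 4 fell. The list was lower than other genes (adjusted p = 0.0416), with an adjusted p of 0.174 with an estimated correlation. Runx2, the transcription factor of osteoblast commitment, and the alkaline phosphatase Alpl, both named after their values were seen, stood at -0.32 (adjusted p = 0.296) and -0.53 (adjusted p = 0.36). In the list of genes that control mineralization 2 of 13 rose and 4 fell, both before and after adjustment over the list alone. The plasma protein Ahsg rose by 2.74, while Tnfrsf11b, the decoy receptor osteoprotegerin, (-2.93), the pyrophosphate-forming enzyme Enpp1 (-1.81) and Bmp4 (-1.23) fell (list adjusted p = 0.245). Among 13 measured Eph receptors and ephrins the receptors Ephb3 (-1.47), Ephb2 (-1.28) and Epha7 (-1.05) fell and 0 rose (5 fell adjusted over the list alone; list adjusted p = 0.000203, and adjusted p = 0.223 with an estimated correlation). Of 15 measured S100 and RAGE genes 0 passed with all libraries, with the receptors Tlr4 at 0.57 (adjusted p = 0.51) and Ager at 0.66 (adjusted p = 0.397). With the vector libraries alone 4 of them rose and 3 fell, where 5273 of all 12994 tested genes passed, so these counts do not set the list apart.

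Of 21 macrophage markers 9 rose and 0 fell (15 rose adjusted over the list alone), with a median of 1.2. The scavenger receptor Cd163 rose from 0.26 ± 0.0333 to 19.3 ± 0.497 FPKM (SD, n = 2), the mannose receptor Mrc1 by 2.08, Cd68 by 1.57 and the receptor Csf1r by 1.35 on the log2 scale. The list had an adjusted p of 2.17e-11 and an adjusted p of 0.137 with an estimated correlation. Fibroblast identity genes went both ways, with 7 of 25 risen and 3 fallen (8 and 7 adjusted over the list alone; list adjusted p = 0.486). Gsn, which severs actin filaments, rose from 190 ± 17.5 to 3382 ± 182 FPKM, and Dpep1 rose by 2.76 and Ly6c1, which has close paralogs, by 2.27 on the log2 scale. Of 8 adipocyte genes 4 rose, adjusted over the list alone too, with the fatty acid binding protein Fabp4 at 3.56 and Cd36, Plin4 and Cebpa between 1.04 and 1.28 (list adjusted p = 0.00041, and adjusted p = 0.136 with an estimated correlation).

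The count of changed genes in vector cells depended on the spread taken from the EphrinB2 libraries. The 4 vector libraries alone gave 5273 genes, 45.6% of them risen against 58.6%, and leaving out both libraries that stood apart gave 5332, and these held 977 and 975 of the 977 genes. Leaving out any 1 vector library gave 170 to 215 genes, and leaving out EphrinB2 osteogenic replicate 1 or 2 gave 1750 or 1744. In the vector libraries alone 20 of 20 glucocorticoid-response genes and 19 of 21 macrophage markers rose, 39 of 41 matrix genes and 22 of 23 cholesterol synthesis genes fell, and 2 osteoblast genes rose while 7 fell. There 24 of 35 cell cycle genes and 8 of 13 Eph receptors and ephrins also fell.

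**Figure D3:**
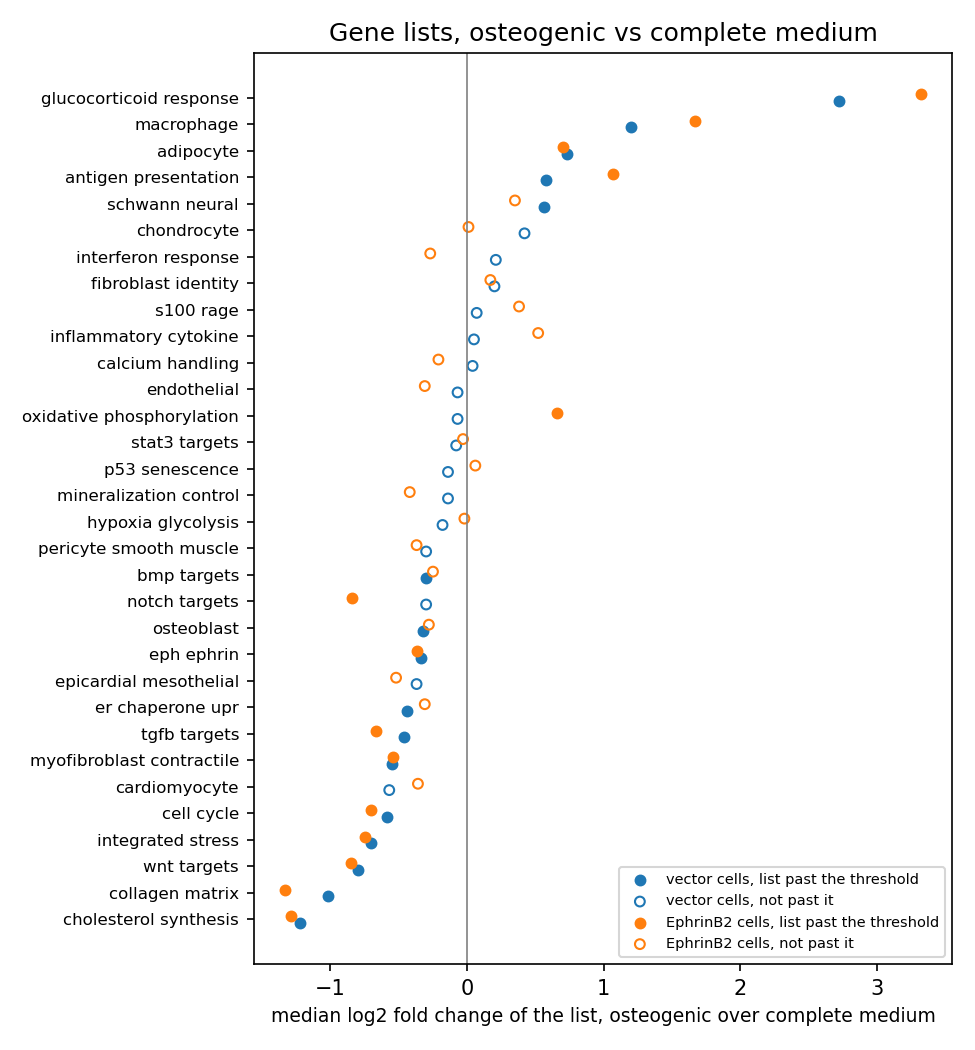
Median log2 fold change, osteogenic over complete medium (x axis), of 32 gene lists (y axis) in vector cells and EphrinB2 cells, with filled points for lists past the camera threshold at the preset correlation. Glucocorticoid response is highest in both, at 2.72 and 3.32, and collagen matrix and cholesterol synthesis are lowest, at -1.02 and -1.33 and at -1.22 and -1.29.

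Osteogenic against complete medium in EphrinB2 cells asks the same of cells that overexpress the ligand. Of the glucocorticoid-response genes 18 of 20 rose and of the macrophage markers 17 of 21, while 27 of 41 matrix, 19 of 23 cholesterol synthesis and 15 of 35 cell cycle genes fell. The macrophage, matrix and cell cycle lists had adjusted p = 0.178, 0.178 and 0.29 with an estimated correlation, and with the EphrinB2 libraries alone 1, 4 and 0 of their genes passed, beside 12 glucocorticoid-response and 0 cholesterol synthesis genes. Of 14 lists past the threshold 2 held with an estimated correlation. Here 826 genes rose and 707 fell (limma, 1533 of 12994), 547 and 425 of them by at least 2-fold. Cbr2 (5.80), F13a1 (5.71), haptoglobin Hp (5.57, SE 0.49), the amino acid transporter Slc38a5 (5.36) and Lyve1 (5.24) were among the largest rises. Col15a1 (-4.59, SE 0.21), the metalloproteinase inhibitor Timp3 (-4.28, SE 0.59), Ccn4 (-4.23), the kinesin Kif26b (-3.87), Eln (-3.61) and Cthrc1 (-3.59) had the largest falls. Adjusted p-values of these 11 genes ran from 4.87e-05 to 0.00641. Hp stood at 21.3 ± 3.46 FPKM in complete and 1199 ± 802 in osteogenic medium (SD, n = 2), so its level differed widely between both osteogenic libraries.

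Of 20 glucocorticoid-response genes 18 rose and 0 fell (20 adjusted over the list alone), with a median of 3.32 and Fkbp5 at 3.94, Sgk1 at 3.50 and Cdkn1c at 4.98 (adjusted p = 1.8e-18, and adjusted p = 0.0194 with an estimated correlation). Of 23 cholesterol synthesis genes 19 fell and 0 rose (20 adjusted over the list alone), among them Sqle (-1.58), Idi1 (-1.76) and Hmgcs1 (-1.80), with an adjusted p of 2.55e-13, and an adjusted p of 0.0194 with an estimated correlation. Of 41 matrix genes 27 fell and 1 rose (35 and 1 adjusted over the list alone), with Col8a2 at -3.36 and Postn at -2.36 (adjusted p = 1.8e-18, and adjusted p = 0.178 with an estimated correlation). Of 21 macrophage markers 17 rose and 1 fell, Cx3cr1 at -0.79, named after its values were seen (18 and 1 adjusted over the list alone), with Cd163 at 3.43 and Mrc1 at 1.70 (adjusted p = 2.41e-09, and adjusted p = 0.178 with an estimated correlation). Of 13 osteoblast genes Omd (1.84) and Ifitm5 (0.85) rose, and 5 fell, with Cdh11 at -2.87 and Col1a1 at -2.35 (3 and 5 adjusted over the list alone; list adjusted p = 0.217). Eph receptors and ephrins fell in 5 of 13 cases and rose in 0, with Ephb3 (-1.60), Ephb2 (-1.73), Epha7 (-1.27) and the ligand Efna5 (-1.44), and 6 fell and 1 rose adjusted over the list alone, but 0 passed with the EphrinB2 libraries alone. That list had an adjusted p of 0.000704, and an adjusted p of 0.314 with an estimated correlation. Cell cycle genes fell in 15 of 35 cases, with Kif20a (-1.56), Prc1 (-1.40) and Top2a (-1.55), and in 20 adjusted over the list alone (adjusted p = 6.92e-09, and adjusted p = 0.29 with an estimated correlation). The chemokine Cxcl5 rose by 2.02, from 5.11 ± 1.01 to 24.3 ± 8.28 FPKM (SD, n = 2). It was 1 of 3 inflammatory cytokine genes of 24 that rose, while Il6 (-1.39) fell (4 and 1 adjusted over the list alone; list adjusted p = 0.185).

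Myofibroblast and contractile genes fell in 6 of 23 cases, with Cthrc1, Itga11 (-2.87) and the myosin Myh10 (-2.01), and 0 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.178 with an estimated correlation). Of 22 TGF-beta targets 6 fell and 1 rose, with Bhlhe40 (-2.58) and Tgfb2 (-1.76), and of 11 Wnt targets 4 fell, with Nkd2 (-2.08) and Apcdd1 (-1.85). Adjusted over the list alone 12 TGF-beta targets fell and 1 rose, and 7 Wnt targets fell. Their list p-values were 5.24e-05 and 2.16e-05, and adjusted p = 0.189 and 0.199 with an estimated correlation. Integrated stress response genes fell in 9 of 20 cases, with Slc7a5 (-1.89), and Notch targets in 2 of 10, Heyl (-1.71) and Hey1 (-0.94). Adjusted over the list alone 12 of the first fell and 2 rose, and 3 of the second fell (adjusted p = 0.000349 and 0.0173, and adjusted p = 0.29 and 0.468 with an estimated correlation). Of 8 adipocyte genes 4 rose, with Fabp4 at 4.36, adjusted over the list alone too (adjusted p = 0.0037, and adjusted p = 0.178 with an estimated correlation). The class I antigen genes H2-K1 (1.72) and H2-D1 (1.92), which have near-identical sequence and may share reads, were the 2 of 14 antigen presentation genes that rose (5 adjusted over the list alone; adjusted p = 0.00322, and adjusted p = 0.542 with an estimated correlation). Oxidative phosphorylation genes were higher as a list (median 0.66, adjusted p = 0.00048, and adjusted p = 0.632 with an estimated correlation) with 0 of 37 called, and lower without the libraries that stood apart (median -0.20).

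This count leaned on the quieter vector libraries for its spread. The 4 EphrinB2 libraries alone gave 153 genes, 152 of them among the 1533, with 72.5% risen against 53.9%, and 12 of 20 glucocorticoid-response genes but 0 cholesterol synthesis genes, 4 matrix genes and 1 macrophage marker passed there. So did 0 Eph and ephrin, cell cycle, inflammatory cytokine, integrated stress response, Notch target and antigen presentation genes, 1 myofibroblast gene, 2 TGF-beta targets, 1 Wnt target, 1 adipocyte gene and 2 osteoblast genes. Gene length also entered, since in the longest genes replicate 2 lay above replicate 1 by 0.38 in complete and 0.52 in osteogenic medium. The library that stood apart was thus higher there in complete and lower in osteogenic medium. This lifts short and lowers long genes in this comparison. Macrophage markers are short, with a median of 1931 bases against 3959 over all tested genes. Their median of 1.67 is thus not like for like with 1.2 in vector cells. Without the libraries that stood apart 3964 genes passed, from 1 EphrinB2 library against 1 with the spread of the vector pairs alone. Without EphrinB2 osteogenic replicate 2 alone 5685 passed, without EphrinB2 complete replicate 2 alone 649, and without any 1 vector library 728 to 780.

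The medium's effect in vector and in EphrinB2 cells was measured on separate libraries. Across the 12994 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.75 and a Spearman correlation of 0.58. Of the called genes 489 rose in both kinds of cells, where 36.4 would if the calls were independent, and 353 fell in both, where 22 would. Both sets of calls use 1 spread per gene from all 8 libraries. They are thus not independent, and the expected numbers can be too low. The 1 gene called in opposite directions, named after its values were seen, was the ribosomal RNA gene n-R5s67, which lay at or below 1.81 FPKM in all 8 libraries. Without the libraries that stood apart the Pearson correlation was 0.88.

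EphrinB2 against vector cells in complete medium asks how overexpressing cells differed at day 7 without osteogenic medium. Beside Efnb2 itself, genes of inflammatory cytokines and macrophage markers lay lower and contractile and matrix genes slightly higher as lists with the preset correlation, but no member of any list passed the threshold. With an estimated correlation these 4 lists had adjusted p = 0.477, 0.546, 0.477 and 0.867, and the matrix median was 0.01 without the libraries that stood apart. The 1 gene called of 12994 (limma) was Mir3569, which was lower (-2.36, SE 0.17, adjusted p = 0.0372) and is named after its values were seen. It is a 58-base microRNA gene (ENSMUSG00000098553, chromosome 7, 30589380 to 30589437) with 5 and 4 estimated reads in the vector libraries and 0 in all others, so its difference rests on a few reads. At an unadjusted p under 0.05 there were 167 genes, 1.3% of those tested. The inflammatory cytokine list was lower (median -0.33, adjusted p = 1.33e-08), with an adjusted p of 0.477 with an estimated correlation. Of its 24 measured members 0 passed over all genes and 1 was lower adjusted over the list alone. That was Cxcl5, a neutrophil chemokine (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), named here after its values were seen, at 16.6 ± 0.676 FPKM in vector and 5.11 ± 1.01 in EphrinB2 cells (SD, n = 2; log2 -1.54, SE 0.25, adjusted p = 0.938). Without the libraries that stood apart Cxcl5 (-1.71, adjusted p = 0.0288) and Efnb2 were the 2 genes called, with 1 EphrinB2 library and the spread of the vector pairs alone.

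The macrophage list was lower (median -0.21, adjusted p = 0.000256) and the myofibroblast and contractile list higher (median 0.22, adjusted p = 0.00158), with the actin gene Actg2 at 0.57 (SE 0.14, adjusted p = 1.0) and calponin, Cnn1, at 0.48 (SE 0.27). Matrix (median 0.11, adjusted p = 0.00552) and calcium handling lists (median 0.12, adjusted p = 0.0263) were higher, and the glucocorticoid-response list was lower (median -0.11, adjusted p = 0.0373). With an estimated correlation these 5 lists had adjusted p-values of 0.546, 0.477, 0.867, 0.88 and 0.521. Without the libraries that stood apart the calcium handling list had a median of -0.07 and the matrix list one of 0.01 (adjusted p = 0.41 and 0.702). The bone protein Spp1 stood at 151 ± 18.7 FPKM in vector and 91.2 ± 6.78 in EphrinB2 cells (log2 -0.72, SE 0.41, adjusted p = 1.0). In all 0 of 13 osteoblast genes passed the threshold, in a comparison where Efnb2 itself did not pass, so changes in them may be missed.

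EphrinB2 against vector cells in osteogenic medium asks the same of cells kept in osteogenic medium. No gene passed (limma, 0 of 12994; 441 at an unadjusted p under 0.05, 3.4%), and the smallest adjusted p was 0.567. Efnb2 had a log2 difference of 2.21. Of the osteoblast list Smpd3 stood at -0.50 (SE 0.22), the parathyroid hormone receptor Pth1r at 0.42 (SE 0.23) and Msx1 at 0.32 (SE 0.22). In all 0 of 13 members passed the threshold, which Efnb2 did not pass either, so changes in them may be missed. The smooth muscle actin Acta2 was at 464 FPKM in vector and 764 in EphrinB2 cells (SD 73 and 205, n = 2; log2 0.70, SE 0.25, adjusted p = 0.567), with Myl9 at 0.83 (SE 0.32) and Tpm2 at 0.96 (SE 0.36). Each was higher in EphrinB2 osteogenic replicate 1 (908.8, 249.2 and 125.2 FPKM) than in replicate 2 (619.2, 138.8 and 55.28 FPKM). Replicate 2 still lay above both vector libraries for each. The receptor Epha2 stood at -0.57 (SE 0.17) and the ligand Efna1 at 0.46 (SE 0.16). S100a13 (0.83, SE 0.44) and S100a16 (0.76, SE 0.38) did not pass either. Their differences lay mostly in EphrinB2 osteogenic replicate 1. S100a13 stood there at 213.8 FPKM, against 73.76 in replicate 2 and 68.5 and 71.88 in the vector libraries. S100a16 stood at 111.7, against 47.82 and 46.23 and 39.39. The oxidative phosphorylation list was the 1 list past the threshold, higher in EphrinB2 cells by a median of 0.62 (adjusted p = 3.19e-08), with 0 of 37 members called and an adjusted p of 0.887 with an estimated correlation. Its members are short, with a median merged exon length of 2101 bases against 3959 over all tested genes, and without EphrinB2 osteogenic replicate 1 its median was 0.09. Without EphrinB2 osteogenic replicate 2, which left only the library that stood apart, 2768 genes passed. Without both libraries that stood apart the 1 gene called was Efnb2, again with 1 EphrinB2 library and the spread of the vector pairs alone. The metalloproteinase Mmp9, named after its values were seen, was second there (-1.84, SE 0.13, adjusted p = 0.238), with 4.15 and 3.88 FPKM in the vector and 1.46 and 0.396 in the EphrinB2 libraries.

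The fold changes of EphrinB2 against vector in the 2 media, which share no library, had a Pearson correlation of -0.11 across genes and one of 0.20 without the libraries that stood apart. With all libraries and the length correction the correlation was -0.04. The libraries that stood apart differed from their partners along gene length in opposite directions in the 2 media. That trend can set the 2 effects apart and enters the interaction. The interaction, which tests whether EphrinB2 altered the response to osteogenic medium, called 0 of 12994 genes (limma; 214 at an unadjusted p under 0.05, smallest adjusted p 0.347). For Efnb2 it was -0.05 (SE 0.67, adjusted p = 0.98). A median difference past the camera threshold was found for 5 lists. It was 0.67 for oxidative phosphorylation (adjusted p = 1.75e-07), -0.28 for matrix (0.000565), -0.23 for calcium handling (0.0198), 0.18 for inflammatory cytokines (0.0379) and -0.58 for interferon response (0.0379). Each had an adjusted p of 0.783 with an estimated correlation. Cxcl5, named after its values were seen, was higher adjusted over the list alone (1.88, SE 0.35, adjusted p = 0.746). S100a4 (1.74, SE 0.75), Smpd3 (-0.86, SE 0.31) and Efna1 (0.47, SE 0.23) had the same adjusted p over all genes. In simulated data, where genes of like mean had the same spread, 0 of 100 genes with a 4-fold interaction were recovered. A change of that size in a single gene may thus be missed, though a real gene with less spread could pass.

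The osteogenic effect in vector cells and the EphrinB2 effect in osteogenic medium share the vector osteogenic libraries with opposite sign. Their fold changes had a Pearson correlation of -0.09 across genes, where 100 simulations without any effect gave -0.26 to -0.20. The simulations lack the medium effect, which widens the real fold changes and draws a correlation toward 0. These correlations are therefore not like for like. The simulated noise also held no trend on gene length. The covariance was -0.02, against -0.014 simulated, a difference of -0.006. No gene was called in both, since none was called in the second.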

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

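The tests of gene length as part of the difference, of the Efnb2 level, of a single library, of the macrophage share, of the fibroblast share and of gene length for the macrophage markers were chosen only after the result was seen. No outlier test was run on single libraries, since each group holds 2.

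EphrinB2 complete replicate 2 and EphrinB2 osteogenic replicate 1 differed from their partners more than the vector libraries did. Gene length is a candidate source of part of this, since it explained 20.9% of the variance of the difference in complete and 30.5% in osteogenic medium, against at most 0.5% in the vector pairs. The tables argue against length as the whole of it, since the closer EphrinB2 pair kept 1.77 times the SD of the wider vector pair after the correction, and against depth, since among genes of at least 1000 reads the SD was at least 10.7 times the counting SD (2.9 and 2.2 in the vector pairs). They also argue against the lower Efnb2 level in osteogenic replicate 1 as the whole of it there, since that library lay 3 times as far from the vector osteogenic mean as its partner. A difference in RNA or library quality and a difference between cultures stay open and were not tested.

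With the preset correlation the oxidative phosphorylation list passed the interaction test (0.67) and was higher in EphrinB2 cells in osteogenic medium (0.62), with adjusted p = 0.783 and 0.887 with an estimated correlation. Without both libraries that stood apart the interaction was -0.11. A single library may be the source, since that median was 0.09 without EphrinB2 osteogenic replicate 1. The length correction gave 0.34, between the bounds set beforehand, so whether gene length is the source stays open. A biological effect of EphrinB2 in that 1 library was not tested apart from the library's own deviation.

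Of 21 macrophage markers 9 rose with osteogenic medium in vector cells (list adjusted p = 2.17e-11, and adjusted p = 0.137 with an estimated correlation), and they did not rise alike. In the vector libraries alone their log2 fold changes ran from -0.05 (Cx3cr1, named after its values were seen) to 4.01 (Cd163). The SD was 12.8 times the median standard error. That ratio decides little, since the scale understates low markers and the libraries of a group may be technical. There 19 of 21 markers rose. Cx3cr1 (7.71 to 7.43 FPKM) and Ms4a7 (6.99 to 6.73 FPKM, also named after its values were seen) did not, while Mrc1 went from 14.9 to 65.8 FPKM. Markers this far apart argue against a larger share of macrophage RNA or a smaller share of fibroblast RNA as the whole change. Gene length as the whole change is argued against by all tested genes in 8 bins by length, of which the median furthest from 0 was -0.07, while the length and GC correction (median 1.22) moved fold changes by an SD of only 0.026 and decides nothing on GC. A smaller share of fibroblast RNA stays open as a part, since the lists of other cell types ran from -0.57 (cardiomyocyte) to 0.73 (adipocyte), as do a larger macrophage share as a part and changed expression in macrophages or fibroblasts, and no sort is given in the sources used here. In complete medium the most abundant of the 21 markers were already present, with Lyz2 at 1490 and C1qa at 150 FPKM in vector cells, both named after their values were seen.

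Other lists that passed the interaction test with the preset correlation were matrix (-0.28), calcium handling (-0.23), inflammatory cytokines (0.18) and interferon response (-0.58), each with adjusted p = 0.783 with an estimated correlation. Without both libraries that stood apart, which keeps the EphrinB2 libraries nearer to vector, their medians were -0.04, 0.02, 0.20 and -0.28. Of the 22 genes that the fixed rule names for EphrinB2 against vector, 4 had both EphrinB2 libraries above both vector libraries in 1 medium and below them in the other, and the interaction did not pass for any (adjusted p = 0.746 each). It was 1.74 for S100a4, -0.64 for Efna5, -0.86 for Smpd3 and 0.48 for Ifitm5. Over all tested genes 419 of 12994 (3.2%) lay this way, where chance gives 5.6%. The rule takes list members with the smallest p in these same comparisons, which favours libraries that lie fully apart. The 4 of 22 are therefore not comparable with the share over all genes. In complete medium Ifitm5 had only 6 and 6 estimated reads in vector and 5 and 1 in EphrinB2 libraries.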

How the results depend on the processing

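The length correction, the length and GC correction, leaving out both libraries that stood apart, library weights and protein-coding genes were chosen only after the data were seen. No paired analysis was possible because no label shares a replicate number between groups. Comparisons are named here by the medium effect in vector or EphrinB2 cells, and by the EphrinB2 effect in complete or osteogenic medium. The cause was not tested except where fewer genes or libraries entered. No gene called for the medium effect in either kind of cell changed sign under any alternative in which it was tested. Of the values of lists and of single genes other than Efnb2, which is given below, under the alternatives fixed beforehand, 3727 kept their direction and side of the threshold, 500 no longer passed, 15 newly passed and 3 turned.

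With an estimated correlation the lists past the threshold numbered 2 and 2 for the medium effect in vector and EphrinB2 cells (16 and 14 with the preset one), 0 and 0 for the EphrinB2 effect in complete and osteogenic medium (6 and 1) and 0 for the interaction (5). The medium effect in vector cells (977 genes) gave 551 with a mean FPKM of at least 5, where fewer genes were tested, 5273 with only the 2 groups compared, 1555 with the length correction, 1568 with length and GC, 5332 without both libraries that stood apart and 5521 with library weights. Risen genes made up 58.6% of the 977, against 45.6%, 45.5% and 48.1% with the 2 groups alone, without both libraries and with weights. The medium effect in EphrinB2 cells (1533 genes) gave 867 with a mean FPKM of at least 5, 153 with the 2 groups alone, 972 with a fold threshold of 2, 3964 without both libraries and 335 with weights. The EphrinB2 effect in complete medium (1 gene) gave 0 with a pseudocount of 0.1, a mean FPKM of at least 5, rescaling, a robust prior, the 2 groups alone, both corrections, weights or protein-coding genes, 13 without a filter and 2 without both libraries. In osteogenic medium (0 genes) it gave 14 without a filter and 1 without both libraries, and the interaction (0 genes) gave 22 without a filter.

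Lists past the threshold for the EphrinB2 effect in complete medium (6) numbered 11 and 10 with the corrections. In osteogenic medium (1) they numbered 2 with a pseudocount of 0.1 or protein-coding genes, 3 with a mean FPKM of at least 5, 5 with rescaling or quantile normalization, 4 with centring or either correction and 9 without both libraries. For the interaction (5) they numbered 3 with a mean FPKM of at least 5 or either correction. Rescaling to a common total moved the median of all genes to -0.151 for the medium effect in EphrinB2 cells, -0.234 for the EphrinB2 effect in osteogenic medium and -0.195 for the interaction.

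The interaction of Efnb2 (-0.05) was 0.35 with a pseudocount of 0.1, 0.06 with rescaling, 0.08 with quantile normalization, 0.12 and 0.11 with the corrections and 0.83 without both libraries. The fall of Efnb2 with medium in vector cells (-1.57) passed with the 2 groups alone, without both libraries and with weights, each at -1.57. Leaving out both libraries leaves 1 library in each EphrinB2 group, the 1 nearer to vector, and a spread from the vector pairs alone. With this Efnb2 also passed for the EphrinB2 effect in complete (2.22) and osteogenic medium (3.05) and for the medium effect in EphrinB2 cells (-0.74). There S100a11 and the calcium handling list turned to 0.20 and -0.07 for the EphrinB2 effect in complete medium, and oxidative phosphorylation to -0.20 for the medium effect in EphrinB2 cells. Interactions turned to -0.06 for S100a11, 0.01 for Myh10, 0.09 for Tlr4, 0.08 for Ephb2, 0.02 for calcium handling and -0.11 for oxidative phosphorylation. The correlations of fold changes became 0.88 between both medium effects and 0.20 between both EphrinB2 effects.

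Leaving out 1 library at a time leaves a lone library that is assumed to vary like the other groups. The medium effect gave 170 (without vector osteogenic replicate 2) to 1750 genes (without EphrinB2 osteogenic replicate 1) in vector cells and 649 (without EphrinB2 complete replicate 2) to 5685 (without EphrinB2 osteogenic replicate 2) in EphrinB2 cells. The EphrinB2 effect gave 0 to 1 in complete and 0 to 2768 in osteogenic medium, the latter without EphrinB2 osteogenic replicate 2. Lists numbered 4 to 11 and 1 to 7 for these. Efnb2 ranged from -1.65 to -1.49 and from -2.46 to -0.78 for the medium effects, from 2.18 to 2.33 and from 1.37 to 3.05 for the EphrinB2 effects, and from -0.89 to 0.79 for the interaction. The interferon interaction ranged from -1.33 to 0.16, and for the EphrinB2 effect in complete medium S100a11 ranged from -0.78 to 0.20 and calcium handling from -0.07 to 0.30.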

Other observations

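The test of a glucocorticoid-like medium was chosen after the result was seen. Several lists not yet described moved with osteogenic medium in vector cells. Integrated stress response genes fell in 6 of 20 cases and rose in 0 (12 and 1 adjusted over the list alone), with the amino acid transporter Slc7a5 (-1.42), Chac1 (-1.40), the pseudokinase Trib3 (-1.15) and Vldlr (-1.37), and a list adjusted p of 5.17e-07 (adjusted p = 0.157 with an estimated correlation). Of 19 endoplasmic reticulum chaperones 1 fell, Canx (-0.82), and the list median was -0.44 (adjusted p = 0.00131, and adjusted p = 0.238 with an estimated correlation). Of 14 BMP target genes 2 fell, Smad6 (-0.96) and Hey1 (-1.17), with list adjusted p = 0.0261 (adjusted p = 0.157 with an estimated correlation). Antigen presentation genes were higher as a list (median 0.58, adjusted p = 0.0117, and adjusted p = 0.633 with an estimated correlation), with 0 of 14 called. Of 5 Schwann and neural markers 2 rose, Cdh19 (1.68) and Cnp (0.78), with list adjusted p = 0.0156 (adjusted p = 0.157 with an estimated correlation).

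The other lists did not pass in vector cells. Calcium handling had 3 of 31 risen, with the channel Trpv4 (1.84) the calcium sensor Stim1 (1.80) and Nfatc2 (1.18), and 1 fallen, Cacna1g (-1.02). Chondrocyte genes had 1 of 7 risen, Cnmd (2.80), and 2 fallen, Matn4 (-2.20) and Cilp (-0.76). STAT3 targets had Lrg1 risen (1.64) and 2 of 15 fallen, Lif (-1.78) and Il6 (-1.78). Inflammatory cytokine genes had 2 of 24 risen, complement C3 (2.02) and Birc3 (1.05), and Il6 fallen, with a median of 0.05 and a test in the other direction (adjusted p = 0.881). Senescence and p53 genes had 2 of 19 risen, Sesn1 (1.03) and Perp (0.90), and 1 fallen, Lmnb1 (-0.88). Notch targets had 2 of 10 fallen, hypoxia and glycolysis genes 1 of 25 risen and 1 fallen, and 0 of 32 interferon response and 0 of 37 oxidative phosphorylation genes passed with all libraries. With the vector libraries alone, which vary less, 0 interferon response genes passed, 1 oxidative phosphorylation gene rose and 6 fell, and 5 antigen presentation genes rose. There 5273 of all 12994 tested genes passed. Median, mean and test differed in sign for endothelial (-0.07, 0.04, up) and pericyte and smooth muscle markers (-0.30, 0.15, down). Markers of other cells went both ways, with 1 of 7 endothelial genes risen and 1 fallen, 1 of 8 pericyte and smooth muscle genes risen, 1 of 7 epicardial and mesothelial genes risen and 1 fallen, 1 of 4 cardiomyocyte genes risen and 0 of 1 lymphocyte genes passed (1 fell with the vector libraries alone).

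The osteogenic medium may have acted as a glucocorticoid, a hormone class often added to such media; its contents are not given in the sources used here. The prediction was that most of the 20 measured glucocorticoid-response genes rise, none fall, and the list holds with an estimated correlation. In vector cells 17 rose and 0 fell, and the adjusted p was 0.00876. The list was fixed beforehand, but the hypothesis was formed and tested on the same libraries, and other agents in the medium were not tested.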
